A study of Mus musculus with 2 samples.

How the data were processed

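Total RNA of mIMCD3 cells, an epithelial line from the mouse inner medullary collecting duct, was compared with and without the fibroblast growth factor FGF23 (10 ng/mL for 4 h) on 2 Agilent two-colour expression arrays. Each array held both RNAs. Per the labels, FGF23 RNA carried Cy3 on array 1 (replicate 1) and Cy5 on array 2 (replicate 2), so the dyes were swapped. The direction of every ratio rests on these labels. The labels do not say that the arrays came from separate cultures or extracts. The p-values therefore measure only spread between these 2 arrays, taken largely over all genes together, which may be technical.

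The deposited scanner output gave, per spot and dye, a mean and a background-subtracted intensity in linear scanner units, made with Feature Extraction 11.5.1.1 per the file headers. It also held a log10 ratio of Cy5 over Cy3 that, per the file headers, the scanner software had background-subtracted and dye-normalized. A p-value of that log ratio, from the software's own error model, was deposited per spot. The deposited files further carried flags for outlier, saturated and well-above-background spots. Probe positions were given on mouse build mm9, per the file headers.

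For the main values, mean signals were background-corrected with normexp (offset 50) on the local background median and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 (R 4.3.3). Each array's log2 ratio was then turned to FGF23 over unstimulated. Outlier and control spots were left out, and spots of a probe were averaged. Probes were kept where they were well above background on both arrays in the FGF23 channel, or on both in the unstimulated channel. This kept 26941 of 55681 probes. A gene was represented by its brightest kept probe, which gave 19220 genes. Symbols came from the array's own annotation, updated through RefSeq transcripts of GRCm38.p6 for the 28026 probes that matched, of which 1651 were renamed. No coordinates of that assembly were used. Exon and UTR positions of the probes were not analysed here.

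Each array had 62976 spots, of which 59305 were not controls. The median mean signal, before background correction, was 52.5 in Cy3 and 69.9 in Cy5 on array 1, and 54.5 and 76.9 on array 2. These values include the background, whose medians were 40 in Cy3 and 37 in Cy5. The share of spots well above background was 48.2% and 48.7% in Cy3 and 54.2% and 55.2% in Cy5. No spot was saturated, and 189 and 201 spots were flagged as outliers. Across genes, the SD of the log2 ratios was 0.15 on array 1 and 0.13 on array 2. The number of arrays limits the precision. The files give both arrays 1 scan time. Batches of culture, extraction or labelling are not given in the sources used here. The 10 spike-in controls had Cy5/Cy3 log2 ratios that differed by at most 0.12 between arrays. The slope of observed on expected spike-in log ratios was 0.851 and 0.852 per the file headers, so folds were compressed.

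The test was limma's lmFit and eBayes on the log2 ratios of both arrays, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. It had 1 residual degree of freedom. In limma, each gene's spread was drawn towards a value fitted over all genes, with 11.9 degrees of freedom. The p-values thus rest mostly on that shared spread and not on the SD printed for a gene. No dye term was fitted, since it would have left no residual degree of freedom. A gene's dye effect cancels in the mean of the arrays and stays in the spread. A rule without a spread estimate counted genes at least 1.5-fold in 1 direction on both arrays. The same count of Cy5 over Cy3, with neither array turned, measured the dye background. For 26 gene lists, the median log2 ratio was set among 10000 random lists of the same size, matched on brightness in 10 bins, with no p-value. The lists, the tests, the naming rule and the alternatives, unless said otherwise, were fixed before the data were examined. Adjusting over a list alone applied Benjamini-Hochberg to that list's measured members only. It was not among the fixed tests and had no correction across the 26 lists.

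Named genes were the 12 per direction with the largest smaller-of-both-arrays log2 ratio of 1 sign, those past the test first and the others filled in with values only. Per list, up to 4 members past the test were named, or the 2 with the largest mean log2 ratio where none passed. A fixed set of FGF receptors, klotho, ERK targets and phosphate, injury and cytokine genes was always named. Unnamed transcripts and predicted genes were not counted among the 12. Members named because they passed over a list alone, outside this rule, were chosen after their values were seen. Some genes that the rule names are not reported here.

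The test was checked on simulated log2 ratios of the same 19220 genes, drawn with the fitted spread, of which 200 were changed. In the first simulated set it called 100% of the 2-fold and 96% of the 1.5-fold changes, and 26 unchanged genes. Over 20 such sets, a median of 9.38% of its calls were unchanged genes, with a range of 2.97% to 21.1%. The share of wrong calls was thus above 5% in the median simulation. Whether the 1 residual degree of freedom caused this was not tested. When the raw FGF23 signal of 200 probes was doubled on both arrays, the median log2 shift was 0.97 for the brighter probes and 0.66 for the dimmer ones.

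Alternatives covered Agilent's processed log ratio, a normexp offset of 0, median centring in place of loess, no filter or a stricter filter on dim probes, and the mean over a gene's probes. Others were each array alone, an intensity trend with a robust prior, limma's treat against a 1.2-fold change, the scanner software's p-values, and a 2-fold threshold. A limma test of the dye contrast, and 3 further gene lists with their own recomputation, were added after seeing the data.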

Results

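The arrays compared mIMCD3 cells given FGF23 with unstimulated cells, to look for roles of this bone-derived hormone in tubule cells other than calcium and phosphate handling. FGF23 is known mainly for lowering renal phosphate reabsorption and vitamin D activation through FGF receptors and the co-receptor klotho. There was 1 comparison, measured on 2 dye-swapped arrays with 19220 genes above background. Of these, 18279 were well above background in both conditions, 398 on both arrays with FGF23 only and 543 on both arrays in unstimulated cells only.

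After 4 h of FGF23, 9 of 19220 genes were higher, among them 3 of the 19 measured hypoxia and glycolysis genes and the metallothionein genes Mt1 and Mt2. Bnip3, a mitophagy receptor induced by low oxygen, rose 2.07-fold (log2 ratio 1.05 ± 0.16, SD, n = 2 arrays). The metal-binding proteins Mt1 and Mt2 rose 1.75-fold and 1.72-fold (0.81 ± 0.24 and 0.78 ± 0.058). Pdk1, a kinase that inhibits pyruvate dehydrogenase, Slc16a3, a lactate exporter, and the hypoxia-inducible gene Ankrd37 rose 1.5-fold, 1.51-fold and 1.55-fold. No gene passed the test as lower, and the largest decrease measured by the naming rule was that of the cyclin Ccnd1, with a log2 ratio of -0.49 ± 0.050 that did not pass.

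In limma's test, 9 genes passed, all of them higher on both arrays. Bnip3 had an adjusted p of 0.00066, and its 3 probes had log2 ratios of 1.05, 1.11 and 0.69. The brightest lies on chromosome 7 from 146082640 to 146082699 (mm9). Mt2 and Mgarp, the latter a mitochondrial protein, each had an adjusted p of 0.0031. Mgarp rose 1.72-fold (0.78 ± 0.079). Mt1 had an adjusted p of 0.0062, but its second, dim probe had a log2 ratio of 0.031. Mt2 and Mt1 lie on chromosome 8, with probes at 96697371 to 96697430 and 96704165 to 96704224 (mm9). Selenbp1, a selenium-binding protein, rose 1.59-fold (0.67 ± 0.0084, adjusted p = 0.010). Slc16a3 (0.60 ± 0.087) and Ankrd37 (0.63 ± 0.17) each had an adjusted p of 0.030, and Pdk1 (0.59 ± 0.083) had 0.033. Both probes of Slc16a3 were higher, at 0.60 and 0.58. The remaining gene that passed was a probe without a gene name, A_55_P2097048, on chromosome X from 13067440 to 13067499 (mm9). It rose 1.92-fold (0.94 ± 0.038, adjusted p = 0.00066).

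**Figure D1:**
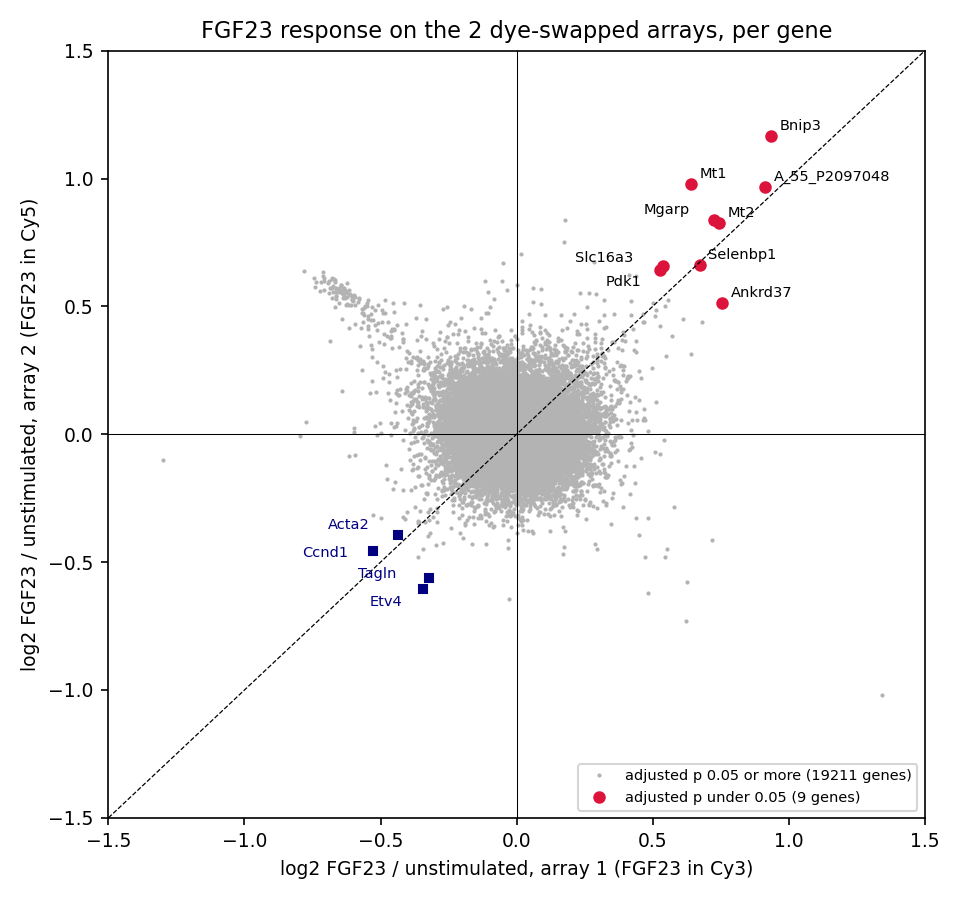
Log2 ratio of FGF23 over unstimulated for each of 19220 genes on array 1 (horizontal) and array 2 (vertical), with the 9 genes past limma's test in red, 4 genes with negative ratios that did not pass in blue, and the line of equal ratios dashed. The red genes lie at or above 0.51 on both arrays, while the group at upper left was brighter in Cy5 on both arrays.

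Genes next in size did not pass. Ndrg1, another hypoxia-inducible gene, had a log2 ratio of 0.54 ± 0.020 at an adjusted p of 0.055. The fucosyltransferase Fut1 had 0.52 ± 0.032, the membrane protease Tmprss6 had 0.51 ± 0.0068, and Lrrc56 had 0.47 ± 0.0037, at adjusted p from 0.066 to 0.11. A second, about equally bright probe of Lrrc56 had 0.26. On the negative side, Ccnd1 had an adjusted p of 0.084. The ETS factor Etv4 had -0.47 ± 0.19 and the smooth muscle actin Acta2 had -0.41 ± 0.028. Traf1, an adaptor of tumour necrosis factor receptors, had -0.42 ± 0.081, and the peptidase Ctsw had -0.41 ± 0.12. Polr1b, a subunit of RNA polymerase I, had -0.40 ± 0.075, although its second, dim probe had 0.15. Ccbe1 (-0.37 ± 0.056), the metalloproteinase inhibitor Timp3 (-0.36 ± 0.053) and the cytokine Il11 (-0.36 ± 0.011) followed. Other kept probes of Ccbe1 had -0.30 and -0.082. The interleukin receptor Il1rl1 had -0.35 ± 0.017, with another kept probe at -0.15. The lymphangiogenic factor Vegfc had -0.35 ± 0.010 and the AP-1 subunit Fosl1 had -0.34 ± 0.0047. Adjusted p for these 11 genes other than Ccnd1 ran from 0.15 to 0.44.

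**Figure D2:**
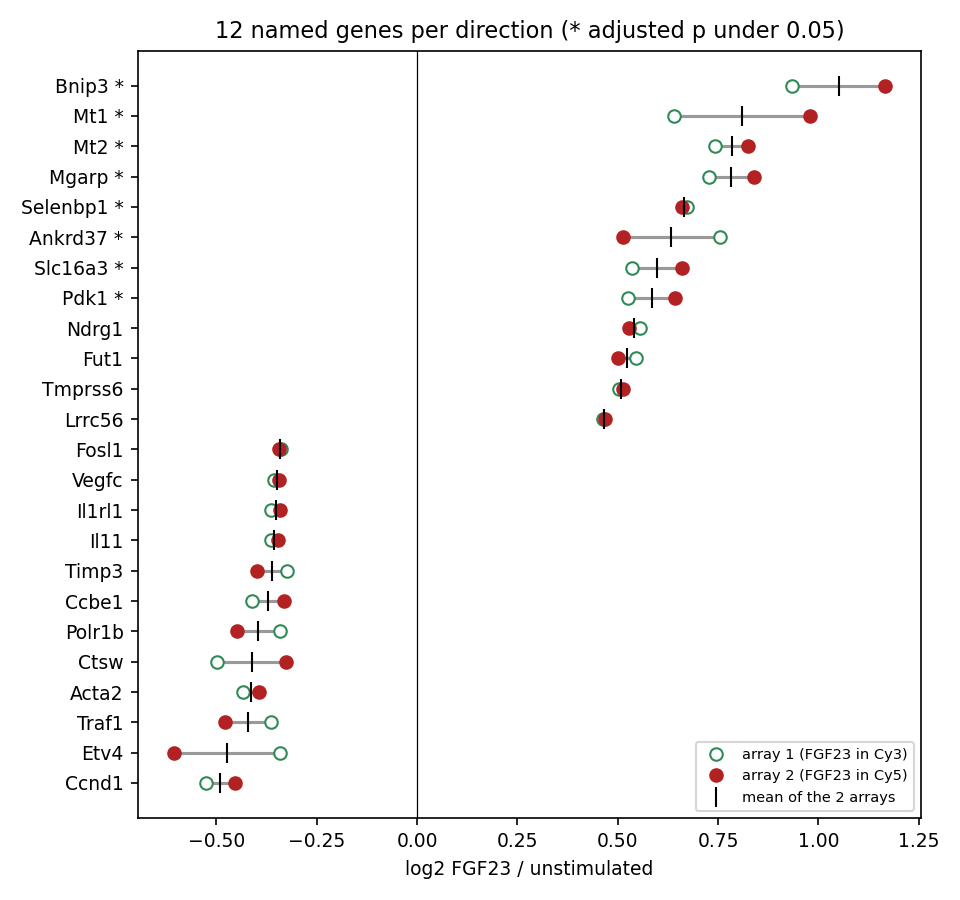
Log2 ratio of FGF23 over unstimulated on array 1 (open) and array 2 (filled) for 12 named genes per direction, with the mean as a bar and a star for an adjusted p under 0.05 in limma's test. Positive genes run up to 1.05 for Bnip3 and negative ones down to -0.49 for Ccnd1, and the stars are all on positive genes.

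At an unadjusted p under 0.05 there were 500 genes higher and 251 lower, where 961 would be met by chance among 19220 tests. No dye term was fitted, so a gene's dye effect, of opposite sign on the turned arrays, widened the spread used in the test. That lowers such a count, but by how much was not tested. By size alone, 6 genes were at least 1.5-fold higher on both arrays and 0 were lower, against 34 and 26 with Agilent's processed log ratio and 15 and 1 with a normexp offset of 0. The dye contrast, which holds no treatment effect, gave 19 such genes, 17 brighter in Cy5 and 2 in Cy3. Across genes, which are not independent replicates, the log2 ratios of the arrays had a Pearson correlation of -0.12 and a Spearman correlation of -0.084, and 46.2% of genes had 1 sign on both. The 9 calls went to 0 with Agilent's processed log ratio and with median centring, and to 51 higher and 20 lower with an intensity trend and a robust prior. In simulations with 200 changed genes and no dye effect, between 2.97% and 21.1% of calls at this threshold were unchanged genes. That share depends on how many genes changed and on the noise drawn, so it gives no error rate for these 9 calls.

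Among the fixed lists, the hypoxia and glycolysis genes had the largest median. Of 19 measured members, 3 rose (Bnip3, Ankrd37 and Pdk1) and 16 did not pass. When adjusted over the list alone, 11 were higher and 0 lower, the others being Vegfa, Slc2a1, Pgk1, Ldha, Ndrg1, Aldoa, P4ha1 and P4ha2. On both arrays 17 members were above 0 and none was below on both. The median log2 ratio was 0.25, at 0.15 on array 1 and 0.35 on array 2, at percentiles 99.99 and 100 of random lists. The glucose transporter Slc2a1 had 0.41 ± 0.20 and the glycolytic enzymes Pgk1 and Ldha had 0.27 ± 0.16 and 0.25 ± 0.15.

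Fibrosis and epithelial-mesenchymal genes had a median of -0.10 over 26 measured members (-0.14 and -0.083 on the arrays). Its percentiles were 0 and 0.02. None passed over all genes. When adjusted over the list alone, 4 were lower, namely Tagln (-0.44 ± 0.17) and Acta2, both actin-cytoskeleton genes of contractile cells, the intermediate filament gene Vim (-0.30 ± 0.15) and Timp3. The profibrotic cytokine Tgfb1 had -0.062 ± 0.17. Among the 26 lists, the hypoxia list was the 1 in the top 2.5% of random lists on both arrays, and this list the 1 in the bottom 2.5% on both.

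Targets of the MAP kinase ERK, which FGF receptors activate, did not pass in either direction. Over 21 measured ERK feedback and output genes the median was -0.059, at percentile 0.38 over the gene means and 7.76 and 1.46 on the arrays. Other lists also lay far out over the gene means, such as collecting duct and ureteric markers (99.48), macrophage markers (99.19) and interferon-stimulated genes (1.25). Of the ERK list, 11 members were below 0 on both arrays and 2 above. When adjusted over the list alone, 2 (Etv4 and Ccnd1) were lower. The ERK phosphatase gene Dusp6 had -0.031 ± 0.016 and the inhibitor gene Spry4 had -0.063 ± 0.031. Spry4's probe was dim (mean log2 intensity 6.48), and a doubled signal gave a median log2 shift of only 0.66 in dimmer probes. Over 31 immediate-early genes the median was -0.0072, and adjusted over the list alone 1 (Egr2) was higher and 1 (Fosl1) lower. Egr1 had 0.26 ± 0.21 and Fos 0.10 ± 0.097. Egr2 had 0.33 ± 0.092, but was well above background on 1 of 2 arrays in unstimulated cells, so this ratio and its call rest partly on background-level signal.

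Klotho (Kl) was not well above background on both arrays in either condition. Neither were the phosphate transporter Slc34a1, the vitamin D enzymes Cyp24a1 and Cyp27b1, and the cytokines Il6 and Tnf. The receptors Fgfr1 (-0.0071 ± 0.00023), Fgfr2 (0.029 ± 0.20), Fgfr3 (-0.084 ± 0.20) and Fgfr4 (0.052 ± 0.16) were measured and did not pass. Fgfr1's 3 probes gave mean log2 ratios of -0.0071, -0.066 and 0.14. Of 20 measured FGF ligands, receptors and klothos, none passed, and none did when adjusted over the list alone. Those with the largest ratios were Fgf21 (0.19 ± 0.33) and Fgf9 (0.13 ± 0.12), the latter well above background on 1 of 2 arrays in unstimulated cells. Of 11 measured phosphate, calcium and vitamin D genes none passed over all genes, and 1, the stanniocalcin Stc2 (0.39 ± 0.10), was higher when adjusted over the list alone. The phosphate transporter Slc20a2 had -0.096 ± 0.20.

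Of 22 measured collecting duct water and sodium transport genes, none passed, nor did any when adjusted over the list alone. The sodium channel subunit Scnn1a had 0.032 ± 0.19, the urea transporter Slc14a2 had 0.21 ± 0.0040 and Fxyd5 had -0.32 ± 0.037. Another kept probe of Slc14a2 had 0.12, at -0.0081 on array 1 and 0.24 on array 2. Collecting duct and ureteric epithelium markers (18 measured) had a median of 0.055, with Lhx1 at 0.23 ± 0.26 and Grhl2 at 0.21 ± 0.063, and none passed either way. Another kept probe of Lhx1 had -0.034. Of 17 tubule injury markers none passed over all genes. When adjusted over the list alone, Lcn2 (0.27 ± 0.047) was higher, and Havcr1 (-0.28 ± 0.068) and Cd44 were lower. Of 25 NF-kB and inflammatory genes 0 passed and 1, Traf1, was lower when adjusted over the list alone, while the NF-kB inhibitor Tnfaip3 had -0.27 ± 0.082. The renin-angiotensin list had 5 measured genes and none passed, with angiotensinogen (Agt, -0.19 ± 0.069) well above background on 1 of 2 arrays with FGF23 and Enpep at 0.14 ± 0.14.

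The unfolded protein and integrated stress response list had 24 measured genes and a median of 0.033. None passed over all genes and 4 were higher when adjusted over the list alone, namely Vldlr (0.48 ± 0.13), Trib3 (0.42 ± 0.15), Ddit4 and Chac1. Interferon-stimulated genes had a median of -0.038 over 24 members, with Xaf1 at -0.16 ± 0.0048. The 27 cell cycle genes, with Tk1 at -0.13 ± 0.044 and Ccnb2 at 0.13 ± 0.019, had a median of -0.0025. The 22 cholesterol genes, with Hsd17b7 at -0.13 ± 0.073 and Stard4 at 0.11 ± 0.17, had a median of -0.0040. In these 3 lists, and in the heat shock, oxidative stress, circadian clock, histone and housekeeping lists, none passed over all genes or when adjusted over the list alone. Medians of those 5 lists were -0.00027, -0.030, 0.053, 0.020 and 0.034. The housekeeping median was -0.022 on array 1 and 0.11 on array 2, with Actb, a very bright probe, at -0.41 and 0.16.

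Markers of other cell types were mostly not well above background on both arrays in either condition. Measured were 6 of 14 proximal tubule, 4 of 10 thick ascending limb and distal tubule, 4 of 10 intercalated cell, 2 of 11 fibroblast, 5 of 12 macrophage and 4 of 10 endothelial markers. None of them passed over all genes or when adjusted over the list alone. The macrophage markers had the largest median, 0.12, with Csf1r at 0.16 ± 0.037 and Cd14 at 0.13 ± 0.15, at percentiles 90.6 and 99.2 of random lists on the arrays. Without the filter on dim probes that median was 0.029. Other kept probes of Csf1r had 0.12 and 0.017.

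**Figure D3:**
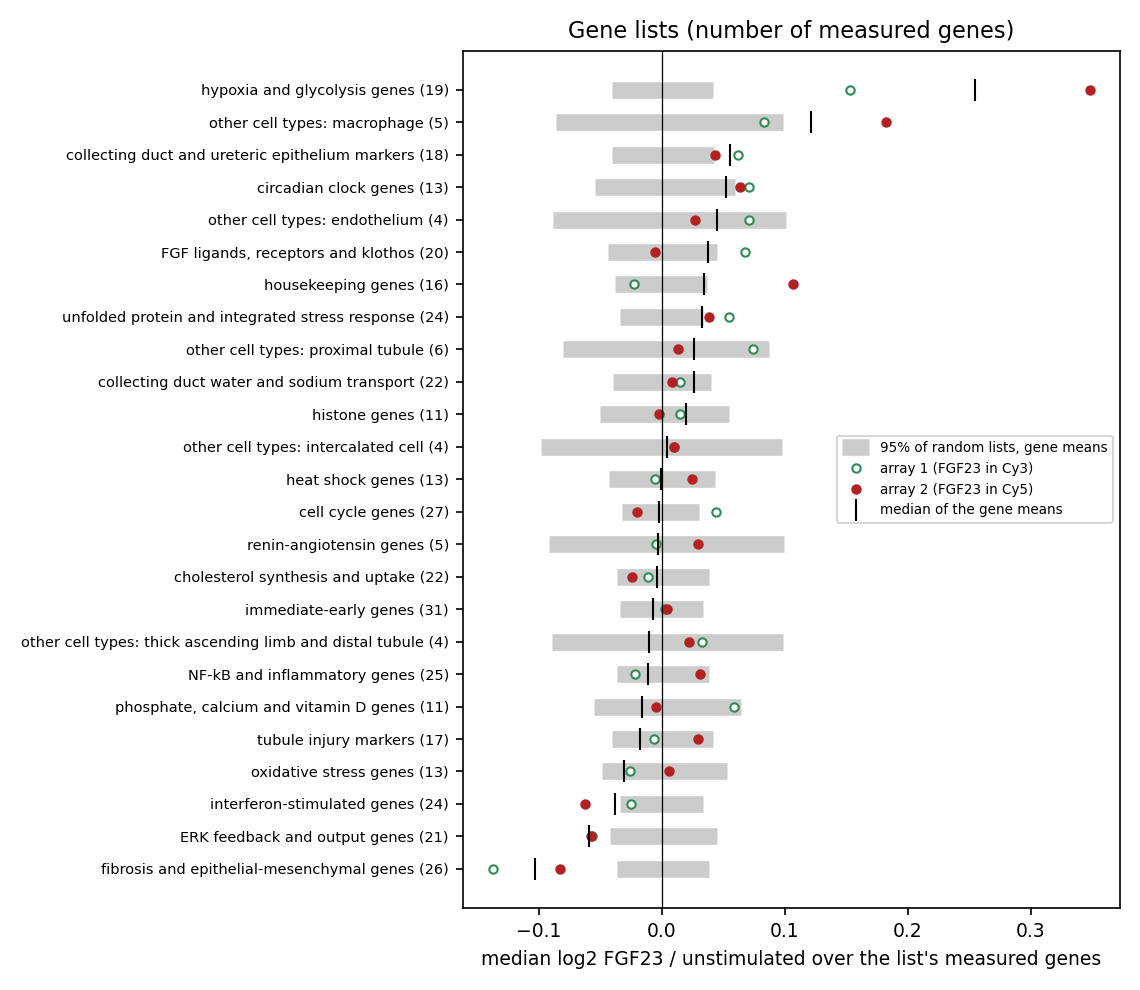
Median log2 ratio of FGF23 over unstimulated per gene list with at least 4 measured genes (number in brackets) on array 1 (open), array 2 (filled) and over the gene means (bar). Grey marks the central 95% of random brightness-matched lists for the gene means, so it applies to the bar and not to the single arrays. The hypoxia and glycolysis list lies at 0.15 and 0.35 on the arrays, and the fibrosis and epithelial-mesenchymal list at -0.14 and -0.083.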

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

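The limma test of the dye contrast and the medians of the lists added later were chosen after the results were seen. Low signal limited much of the array, since at most 55.2% of spots were well above background in either dye. The median of the hypoxia and glycolysis list ran from 0.22 to 0.27 over the processing alternatives, and was 0.15 on array 1 and 0.35 on array 2. The cause of the following differences was not tested. Genes past the test numbered 0 with Agilent's processed log ratio and 0 with median centring, where Bnip3 had log2 ratios of 1.12 and 1.04. With median centring 6 of the 9 genes were above 0 on both arrays, and with Agilent's log ratio all 9 were. They numbered 5 with a normexp offset of 0, where 3 of the 9 remained (Bnip3, Mgarp and A_55_P2097048), and 2 with treat, all higher. Averaging a gene's probes gave 16 higher and 1 lower (Ccnd1) and lost Mt1 (0.42). An intensity trend with a robust prior gave 51 higher and 20 lower, with all 9 kept. Without a filter or with the stricter filter there were 10, which kept all 9. The scanner's p-values gave 13, with 8 of the 9, against 77 genes of opposite direction on the arrays. In limma the dye contrast had 131 genes past the threshold, 0 with Agilent's log ratio or offset 0, 16470 with median centring and 81 over averaged probes. Genes at least 1.5-fold on both arrays numbered 34 higher and 26 lower with Agilent's log ratio, 15 and 1 with offset 0, and 0 and 0 with median centring. At 2-fold there were 0. On a single array the split went opposite ways, with 14 higher and 85 lower on array 1 and 34 higher and 5 lower on array 2. In the dye contrast this count was 86 with Agilent's log ratio, 41 with offset 0, 6878 with median centring, 11 over averaged probes and 1 at 2-fold. Median centring leaves the dye's dependence on brightness in place, as its construction shows. The correlation of the arrays across genes was -0.019, -0.066 and -0.78 with Agilent's log ratio, offset 0 and median centring. It was -0.11 without a filter, -0.14 with the stricter filter and -0.076 over averaged probes. The immediate-early median was 0.023, -0.013 and -0.027 with Agilent's log ratio, offset 0 and median centring, -0.012 without a filter, -0.016 with the stricter filter, -0.00025 over averaged probes, and 0.0028 to 0.0045 on single arrays. The ERK list median was -0.072, -0.065 and -0.073 with Agilent's log ratio, offset 0 and median centring, -0.046 without a filter, -0.062 over averaged probes, and -0.0571 to -0.0569 on single arrays. Fgfr1 was at 0.023 over averaged probes. Of the values of single genes under an alternative, 602 kept their side of the threshold or, on 1 array, moved by less than the spread. Another 25 lost the threshold, 6 gained it, and 3 besides that of Fgfr1 changed sign under a processing alternative, none of which had passed. Sign changes on 1 array, such as that of Fgf21 (0.42 on array 1 and -0.050 on array 2), are among the 602. Of the other list medians, 160 moved by less than the spread of the arrays and 48 by more.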

Other observations

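The tests of dye bias and of exchanged labels were chosen after the results were seen, and the second hypoxia, YAP and SRF, and ribosome biogenesis lists were written after a first look at the top genes but before their own values were seen. Ribosome biogenesis genes, which the fixed lists did not cover, were low as a group. Of 35 measured members, 29 were below 0 on both arrays and 0 above 0 on both, with a median log2 ratio of -0.12. Rrp9 had -0.25 ± 0.11, Nop16 -0.24 ± 0.17 and the nucleolin gene Ncl -0.23 ± 0.19 (SD, n = 2 arrays). None passed limma's test over all genes or when adjusted over the list alone, and 9 were lower at an unadjusted p under 0.05. These members were chosen after their values were seen.

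The higher level of hypoxia and glycolysis genes is hard to reconcile with gene-specific dye bias, since the dyes were swapped and the lower of the list's percentiles on the arrays was 99.99. A second list of 34 measured hypoxia-inducible genes, which shares none with the first, had a median of 0.10 (0.044 on array 1 and 0.13 on array 2) and a lower percentile of 98.37, so the pattern may reach beyond the genes first seen, although none of them passed by itself. A denser culture or one with less oxygen remains a candidate explanation. YAP and SRF target genes, which fall in dense cells, had a median of -0.062 over 36 genes (-0.10 on array 1 and -0.069 on array 2) and a higher percentile of 0.01. They bear on density and not on oxygen, and their list was written after a first look at the top genes. A direct effect of FGF23 could give the same values. It was not tested apart from these culture differences, since the labels do not name more than 1 pair of cultures.

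Etv4, Fosl1 and Ccnd1, which FGF signalling usually raises, had negative ratios. An exchange of the RNA labels on both arrays would turn the sign of every ratio, those of the 9 genes past the test and of the hypoxia, fibrosis and ribosome biogenesis lists included. The higher of the ERK list's percentiles on the arrays was 7.755, but this decides nothing, since the list holds Etv4 and Ccnd1 and a true decrease would lower it as an exchange would. The immediate-early list, to which Fosl1 belongs, does not decide it either, with 11 of 31 members above 0 on both arrays and 10 below 0 on both. The labels' direction was kept, and neither an exchange nor a decrease with FGF23 was excluded.

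Polr1b, Srm and Dkc1, genes of an RNA polymerase I subunit, spermidine synthase and the pseudouridine synthase dyskerin, had log2 ratios of -0.40 ± 0.075, -0.24 ± 0.0052 and -0.27 ± 0.047, none past the test. They prompted the ribosome biogenesis list, whose median had a higher percentile of 0.01, and whose median ran from -0.15 to -0.095 over the processing alternatives and single arrays. A coordinated decrease of this gene group may thus accompany the treatment. Whether FGF23 or a difference between the cultures, such as density, lies behind it was not tested.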
